A study of Mus musculus with 24 samples.

How the data were processed

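RNA-seq and ATAC-seq were measured in cultured mouse periosteal cells of 2 genotypes, with and without Dox, in 8 groups of 3 samples labelled as technical replicates. The labels describe RNA purified on columns and made into polyadenylated-RNA libraries, and ATAC-seq libraries made from transposed nuclei. The submitters' processing notes name HISAT2, Picard, featureCounts and DESeq2, tools of RNA-seq, and Bowtie2, SAMtools, MACS2, bedtools, DiffBind and HOMER, and the mm10 genome build. Their versions, order and settings, the transposase shift and whether peaks were called on pooled samples are not given in the sources used here.

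The RNA-seq signal per gene and sample is a normalised read count that the authors made by dividing read counts by 1 factor per sample, as the deposited columns and their means show. The deposited log2 fold changes and p-values of the RNA-seq tables come from DESeq2, per the file headers and the submitters' processing notes, and a linear fold (ratio of Dox to untreated) stands beside them in the wild-type table, per the file headers. The ATAC-seq tables hold log2 concentrations per group and site, their difference as a log2 fold, and p-values with an FDR, which the authors made with DiffBind per the file headers. The sites of wild-type cells come as other text fields of joined values, per the file headers, read in the order of the YAPCA sheet. The gene set scores per sample, their mean differences and bootstrap p-values are the authors' own, and the tool behind them is not given in the sources used here.

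The YAPCA RNA-seq table holds 35975 genes. Each column proved to be whole multiples of a single value, and dividing by it gave whole reads for 100% of values at a tolerance of 0.01 read, between 16351891 and 28734643 reads a library, which sets the precision of a value. The wild-type table lists only the 98 genes with a DESeq2 adjusted p below 0.05. For the YAPCA sites, a second sheet for chromosome 3 has the headings of its groups exchanged relative to the main sheet for all 1932 shared sites, while the sheet for chromosome 1 has the same order for all 2321. The order of the main sheet was kept, in which the fold is the Dox group minus the untreated group within 0.01. Columns of per-sample values left without a sample numbered 0. Values of 27 lines of the YAPCA RNA-seq table are named by a date in place of a gene. These stayed in the tests, where 21 were tested and 6 called, and none is named. The reads of replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 1.79 to 3.35. Each library was counted as a sample, although such a spread does not show that the samples are separate cultures.

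YAPCA RNA-seq was tested on log2(normalised read count + 1) with limma 3.58.1 in R 4.3.3 (moderated test with an intensity trend, two-sided, Benjamini-Hochberg adjusted p below 0.05) over the 13477 genes with a mean of at least 10. A log2 change on this scale understates the change of low genes. A count test was planned if the table held counts, and limma if it held normalised counts, so the unit decided the test. As alternatives DESeq2 1.42.0 and edgeR 4.0.16 (quasi-likelihood) were run on the recovered whole reads, calling 2843 and 3824 genes, and TMM scaling, pseudocounts of 0.5 and 5, other filters and thresholds, a block for the replicate number and leaving out each library were tried. The 21 gene lists, with 475 of 477 members matched to the table, were fixed before the data were examined, as were the named-gene rule and the tests unless said otherwise. Lists with at least 5 tested members were tested with limma's camera at its preset correlation of 0.01, adjusted over the 17 lists. camera with an estimated correlation, fry, which asks whether the genes of a list move on balance in a single direction and compares them with no other genes, and a rank-based form were alternatives. With an estimated correlation camera takes its degrees of freedom from the few libraries, not from the many genes, so it has less power. Member counts were adjusted over all tested genes and over the list alone.

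The named genes of YAPCA RNA-seq are Yap1, Ccn1, Ccn2, Ankrd1 and Bmp4, then the 10 largest rises and 10 largest falls among genes that passed with a mean of at least 100 and no overlap between groups, leaving out predicted genes, then up to 4 members of each list by adjusted p. For wild-type RNA-seq they are the 5 largest rises and 5 largest falls by the same filters, for ATAC-seq the 5 gained and 5 lost sites with the smallest FDR per genotype and the sites of Ccn1, Ccn2, Ankrd1, Amotl2, Lats2, Bmp4 and Yap1, and for the gene set scores the 5 highest and 5 lowest per genotype. Other members of a list are named as examples. Some genes that the rule takes are not reported here.

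In wild-type RNA-seq the authors' DESeq2 values were used as deposited, since a test over genes listed because they passed would not be a test. Sites were assigned with Python 3.11.15 and pandas 2.3.3 to the nearest of 34610 genes of the GRCm38 reference table, by the distance between the centre of the site and the gene span, within 50 kb. The transcription start was planned for this distance, but the table gives spans without strand. Coordinates are 1-based in mm10 (GRCm38), and exons, introns and UTRs were not told apart. Of the tested genes 96.6% had coordinates. Shares of genes with a site were compared by Fisher's exact test, two-sided (scipy 1.17.1), against tested genes that did not pass, and a logistic model was fitted with statsmodels 0.14.6. The planned test of TEAD and AP-1 motifs needs genome sequence and was not run.

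The limma test with its gene-list test, edgeR, the assignment of sites to genes and Fisher's test were each tested on simulated data. The other steps were not. In data made like the YAPCA RNA-seq libraries, over 13477 genes, limma recovered 32 of 68 genes changed by a log2 change of 0.25, 54 of 66 changed by 0.5 and 62 of 66 changed by 1. It made 16 false calls among 164 (edgeR made 22 among 169), and the changed list was called with 0 of 16 unchanged lists. Genes were simulated independently, so this does not test camera where genes of a list are correlated. The estimated correlation in the real lists reached 0.684, for the mitochondrially encoded genes. Of 2000 sites simulated inside genes for the join with YAPCA RNA-seq, 98.8% were assigned to their gene, and Fisher's test gave an odds ratio of 0.977 (p = 0.662) where none was planted.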

Results

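Periosteal cells, which line the outer surface of bone and expand early in fracture repair, were cultured from wild-type mice and from mice with a doxycycline-inducible transgene for a constitutively active form of YAP, the transcriptional co-activator restrained by the Hippo kinases. The transgenic cells are called YAPCA here. Cells of both genotypes were left untreated or given 1 µM doxycycline (Dox), and RNA-seq and ATAC-seq, which reads open chromatin, were carried out on each, giving 8 groups of 3 samples and 24 samples in all. The labels call the samples of a group technical replicates, so p-values here measure only the spread between these samples, which may be technical. The YAPCA RNA libraries held 28734643, 24858356 and 16351891 reads counted over genes without Dox and 27482996, 23267531 and 20771096 with Dox. The wild-type RNA table used here lists 98 genes only, and the ATAC-seq tables give a mean per group and site, so the total depth of those libraries is unknown. In wild-type untreated RNA replicate 2, 1 read stood for 1.67 normalised read counts, against 0.829 to 0.991 in the other wild-type RNA libraries. That library was thus the shallowest of them.

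The first comparison asked which genes responded to Dox in YAPCA cells. Yap1 itself was at 5041 ± 94.7 normalised read counts without Dox and 4798 ± 86.3 with Dox (SD, n = 3 per group), a log2 change of -0.07 ± 0.028 (SE) that did not pass (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0697). Yap1 passed only when Dox replicate 3 was left out, at -0.09, or with a replicate block. Whether reads of the transgene are counted under Yap1 is not given in the sources used here, so this value does not check the labels. Ccn2 (listed as Ctgf) and Ccn1 (listed as Cyr61), secreted matrix-associated proteins long used as readouts of YAP activity, rose from 39023 ± 4661 to 67145 ± 3902 and from 24520 ± 1550 to 37241 ± 1464 normalised read counts. Their log2 changes were 0.79 ± 0.062 and 0.60 ± 0.039 (SE; limma, adjusted p = 9.98e-08 and 1.06e-08). Ankrd1, an ankyrin-repeat protein of stretched muscle and a direct YAP target, rose from 2401 ± 162 to 3681 ± 249, a log2 change of 0.62 ± 0.049 (limma, adjusted p = 1.26e-07). Bmp4, a bone morphogenetic protein, rose from 14.2 ± 6.07 to 59.1 ± 11.3 normalised read counts, a log2 change of 2.03 ± 0.27 at a low level (limma, adjusted p = 3.87e-05).

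The largest rise among genes with a mean of at least 100 normalised read counts was that of Prrt4, with a log2 change of 1.44 ± 0.13 (SE). Clca3a1, of the chloride channel regulator family, rose by a log2 change of 1.28 ± 0.077, and Spry1, a feedback inhibitor of receptor tyrosine kinases, rose by 1.27 ± 0.055, from 427 ± 26.4 to 1029 ± 17.2 normalised read counts (SD, n = 3). Ereg, a ligand of the EGF receptor, rose by 1.22 ± 0.061, Edn1, the precursor of the vasoconstrictor endothelin-1, by 1.19 ± 0.099 and the cytokine gene Il6 by 1.15 ± 0.094. Adamts5, a protease that cleaves aggrecan, rose from 3890 ± 321 to 9150 ± 790 normalised read counts, a log2 change of 1.23 ± 0.055. Ctnnd2, a catenin of cell junctions, rose by 1.25 ± 0.12 and Pdzd2 by 1.11 ± 0.15.

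Among the falls, Gas1, a membrane protein first known from growth-arrested cells and a co-receptor of hedgehog signalling, fell from 2090 ± 247 to 693 ± 43.4 normalised read counts (SD, n = 3), a log2 change of -1.59 ± 0.067 (SE). Ddit4, a stress-induced inhibitor of mTORC1, had a log2 change of -1.49 ± 0.060, and Ednra, an endothelin receptor, one of -1.33 ± 0.14. Sp7, which encodes the osteoblast transcription factor osterix, fell from 327 ± 11.5 to 162 ± 7.84, a log2 change of -1.01 ± 0.083. Il1rn, the antagonist of the interleukin-1 receptor, fell from 2189 ± 180 to 1084 ± 97.4, a log2 change of -1.01 ± 0.061. Crocc2 (-1.22 ± 0.084), the globin gene Cygb (-1.09 ± 0.10), the kinesin gene Kif21b (-1.08 ± 0.11), Plin4, which coats lipid droplets (-1.03 ± 0.12), and the immediate-early transcription factor gene Egr3 (-1.02 ± 0.13) made up the rest. For the rises and falls given by size, the largest adjusted p was that of Pdzd2, 5.03e-05 (limma with Benjamini-Hochberg adjustment), and the values of the groups did not overlap.

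**Figure D1:**
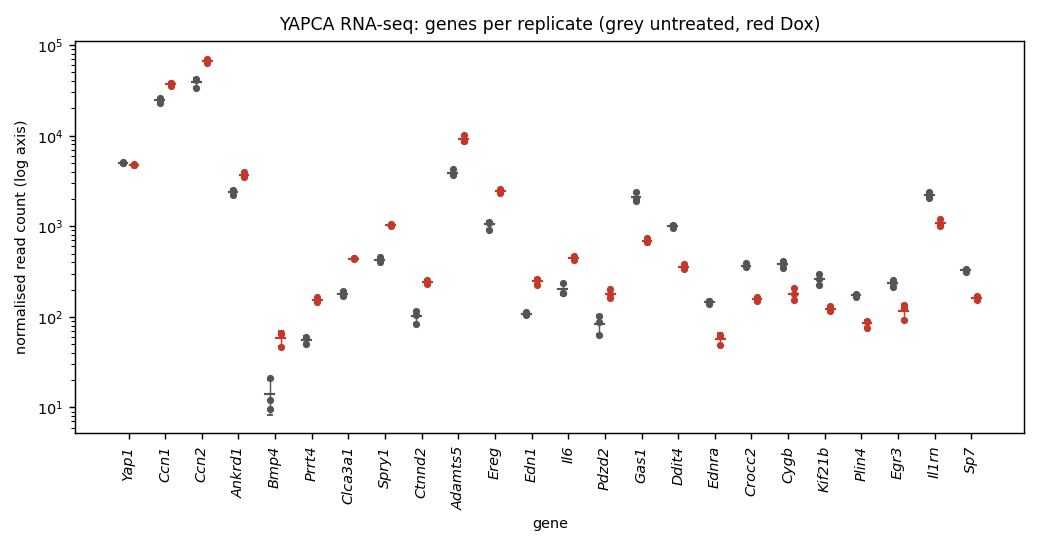
Normalised read counts (log axis) of 24 genes in YAPCA cells, with a point per replicate (grey untreated, red Dox, n = 3 each) and a bar for the mean ± SD. Ccn2 sits at a mean of 39023 untreated and 67145 with Dox, and Gas1 at 2090 and 693.

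Of the 22 genes in the list of YAP/TEAD targets, 13 rose, 1 fell and 8 did not pass. Besides Ccn1, Ccn2 and Ankrd1, Lats2, a kinase that restrains YAP, rose from 2940 ± 46.2 to 4782 ± 22.8 normalised read counts (log2 change 0.70 ± 0.028, SE). Crim1, a transmembrane regulator of BMP ligands, rose by a log2 change of 0.49 ± 0.028 and Amotl2, an angiomotin family member that binds YAP, by 0.43 ± 0.030. The member that fell was F3, tissue factor, at -0.12. Adjusted over the list alone, 14 rose and 2 fell, and the list as a whole lay above the other genes (camera, adjusted p = 4.52e-08; adjusted p = 0.0976 with an estimated correlation). Of 19 Hippo pathway components, 10 rose, 1 fell and 8 did not pass, and adjusted over the list alone 10 rose and 2 fell (camera, adjusted p = 6.17e-05; adjusted p = 0.217 with an estimated correlation). Amot, another YAP-binding angiomotin, rose by a log2 change of 0.88 ± 0.036, the TEAD cofactor gene Vgll3 by 0.60 ± 0.025, Tead1 by 0.35 ± 0.024 and Stk4, which encodes the Hippo kinase MST1, by 0.43 ± 0.041. Tead2 was the member that fell, at -0.22.

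Of 13 osteoblast genes tested, 0 rose, 6 fell and 7 did not pass (limma; 0 and 6 adjusted over the list alone). Col1a1 and Col1a2, the chains of type I collagen, had log2 changes of -0.47 ± 0.029 and -0.21 ± 0.026, and the bone matrix gene Spp1 one of -0.31 ± 0.023, beside the fall of Sp7. The list lay below the other genes (camera, adjusted p = 6.11e-05; adjusted p = 0.0976 with an estimated correlation). Among collagens and other matrix genes, 3 rose, 15 fell and 9 did not pass, and adjusted over the list alone 4 rose and 15 fell (camera, adjusted p = 0.000197; adjusted p = 0.25 with an estimated correlation). Col6a2 and Col6a3, chains of type VI collagen, had log2 changes of -0.47 ± 0.038 and -0.32 ± 0.026. The thrombospondins parted, with Thbs2 at -0.43 ± 0.026 and Thbs1 at 0.39 ± 0.030. Of 18 periosteal and skeletal progenitor genes, 2 rose, 7 fell and 9 did not pass (2 and 8 adjusted over the list alone; camera, adjusted p = 0.0152; adjusted p = 0.25 with an estimated correlation). The receptor gene Pdgfra had a log2 change of -0.47 ± 0.036, the chemokine gene Cxcl12 one of -0.39 ± 0.030, the limb mesenchyme factor Prrx1 one of -0.33 ± 0.027 and the matrix gene Postn one of -0.23 ± 0.026, while the integrin gene Itgav rose by 0.15 and the TGF-beta co-receptor gene Eng by 0.10. A rank-based form of the test did not call this list (adjusted p = 0.105).

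The chondrocyte list had 1 rise, 4 falls and 7 genes that did not pass, with the same counts of 1 and 4 adjusted over the list alone (limma's camera test, adjusted p = 0.175). Sox9, the master transcription factor of cartilage, had a log2 change of -0.59 ± 0.086, Col2a1 one of -0.18 ± 0.033, Sox5 one of -1.25 ± 0.31 at a level of 23.4 ± 7.85 against 8.997 ± 1.13 normalised read counts, and the cartilage matrix gene Comp one of -0.24 ± 0.068. Comp was not called by DESeq2, in the authors' deposited table or on the recovered reads. The adipocyte list had 1 rise, 4 falls and 3 genes that did not pass, again 1 and 4 adjusted over the list alone (limma's camera test, adjusted p = 0.349). The adipogenic transcription factor genes Cebpa, Cebpb and Zfp423 had log2 changes of -0.47 ± 0.056, -0.60 ± 0.084 and -1.09 ± 0.17, and Plin2, a lipid droplet coat, rose by 0.18 ± 0.032.

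Growth factors and their receptors moved both ways, with 11 rising, 5 falling and 10 not passing (11 and 7 adjusted over the list alone; camera, adjusted p = 0.111). Besides Ereg, Csf1, the growth factor of macrophages and osteoclast precursors, rose from 77242 ± 2353 to 109209 ± 787 normalised read counts (log2 change 0.50 ± 0.026), and Hgf, hepatocyte growth factor, fell from 2321 ± 123 to 1362 ± 85.2 (log2 change -0.77 ± 0.047). Of the matrix proteases and inhibitors, 5 rose, 7 fell and 8 did not pass (5 and 8 adjusted over the list alone). Besides Adamts5, the rises included Plau, urokinase, at 0.72 ± 0.028 and Adamts1 at 0.67 ± 0.042, and the gelatinase gene Mmp2 fell by 0.23 on the log2 scale. This list had a median log2 change of -0.05 and a mean of 0.10, and the camera test gave a downward direction (adjusted p = 0.89).

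In the BMP list 7 genes rose, 9 fell and 11 did not pass (11 and 9 adjusted over the list alone). The BMP antagonist gene Fst rose by a log2 change of 0.41 ± 0.037 and the inhibitory Smad7 by 0.25 ± 0.034, while Id3, a transcriptional target of BMP signals, had a log2 change of -0.33 ± 0.029 and the antagonist Grem1 one of -0.25 ± 0.029. The list median was -0.003 and the mean 0.113, and camera gave an upward direction (adjusted p = 0.891). In the WNT list 4 rose, 9 fell and 16 did not pass (6 and 9 adjusted over the list alone; camera, adjusted p = 0.257). The receptor gene Fzd5 rose by 0.45 ± 0.049 and the secreted modulator Dkk2 by 0.75 ± 0.098, and Dkk3 and Fzd1 had log2 changes of -0.31 ± 0.038 and -0.34 ± 0.049. Genes of inflammation and interferon also moved both ways, with 6 rising, 5 falling and 12 not passing (6 and 5 adjusted over the list alone; camera, adjusted p = 0.491). Ccl2 and Ccl7, which attract monocytes, rose by log2 changes of 0.67 ± 0.037 and 0.48 ± 0.038, beside the rise of Il6 and the fall of Il1rn.

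The cell cycle genes that passed changed by small amounts. Of 42 S phase genes, 9 rose, 1 fell and 32 did not pass (8 and 1 adjusted over the list alone; camera, adjusted p = 0.0152; adjusted p = 0.25 with an estimated correlation). Rrm2 and Rrm1, subunits of ribonucleotide reductase, rose by log2 changes of 0.22 ± 0.028 and 0.17 ± 0.025, and the replication genes Cdc45 and Mcm3 by 0.19 ± 0.045 and 0.13 ± 0.032. Of 51 G2/M genes, 8 rose, 12 fell and 31 did not pass (9 and 12 adjusted over the list alone; camera, adjusted p = 0.366). Anln and Tmpo rose by 0.18 ± 0.026 and 0.17 ± 0.030, and the condensin gene Ncapd2 and the kinetochore gene Cenpf had log2 changes of -0.24 ± 0.032 and -0.22 ± 0.044.

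The list of ATF4 stress targets, fixed because Dox is known to disturb mitochondrial translation, had 1 rise, 9 falls and 9 genes that did not pass (1 and 9 adjusted over the list alone; camera, adjusted p = 0.00015; adjusted p = 0.0976 with an estimated correlation). Besides Ddit4, the pseudokinase gene Trib3 had a log2 change of -0.76 ± 0.062, Ddit3, the stress factor CHOP, one of -0.65 ± 0.059 and Atf5 one of -0.31 ± 0.029, and the amino acid enzyme genes Asns, Psat1 and Phgdh did not pass. Of 11 mitochondrially encoded genes, 3 rose, 0 fell and 8 did not pass (limma; 3 and 0 adjusted over the list alone). These were mt-Nd2 at a log2 change of 0.46 ± 0.052, mt-Nd4 at 0.22 ± 0.053 and mt-Cytb at 0.24 ± 0.060, and of the 3 mt-Nd2 alone had groups without overlap and was called by DESeq2 too. The list passed in camera (adjusted p = 0.028; adjusted p = 0.574 with an estimated correlation) and lost its call when untreated replicate 1, untreated replicate 2 or Dox replicate 2 was left out (adjusted p = 0.22, 0.0803 and 0.104) or fry was used (adjusted p = 0.2955).

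Of the endothelial list 5 genes were tested and 0 passed (limma; 0 adjusted over the list alone; 1, Tek, at an unadjusted p below 0.05; camera, adjusted p = 0.732), with Tek, an angiopoietin receptor gene, at 31.0 ± 7.65 and 49.4 ± 15.2 normalised read counts. Tek passed when untreated replicate 2 or Dox replicate 2 was left out, at log2 changes of 0.82 and 0.90. Of the macrophage list 4 were tested and 0 passed (limma; 0 adjusted over the list alone; 1, Cd14, at an unadjusted p below 0.05), with Csf1r at 205 ± 20.4 and 198 ± 6.43. Both epithelial genes tested rose, Krt19 from 479 ± 25.7 to 742 ± 43.4 (log2 change 0.63 ± 0.060) and Krt7 by 1.23 ± 0.29 at 12.7 ± 4.61 against 29.995 ± 4.43. Of 4 osteoclast genes, the integrin gene Itgb3 and the transcription factor gene Nfatc1 had log2 changes of -0.77 ± 0.069 and -0.49 ± 0.049, and Acp5 and Oscar did not pass. Of 4 muscle genes, Acta1 alone passed, at a log2 change of -0.15 ± 0.052 with overlapping groups, and it was not called by DESeq2. Both edgeR and DESeq2 also called 0 of the endothelial genes Tek and Kdr and 0 of the 4 macrophage genes. The counts adjusted over each list alone were the same for these 3 lists.

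**Figure D2:**
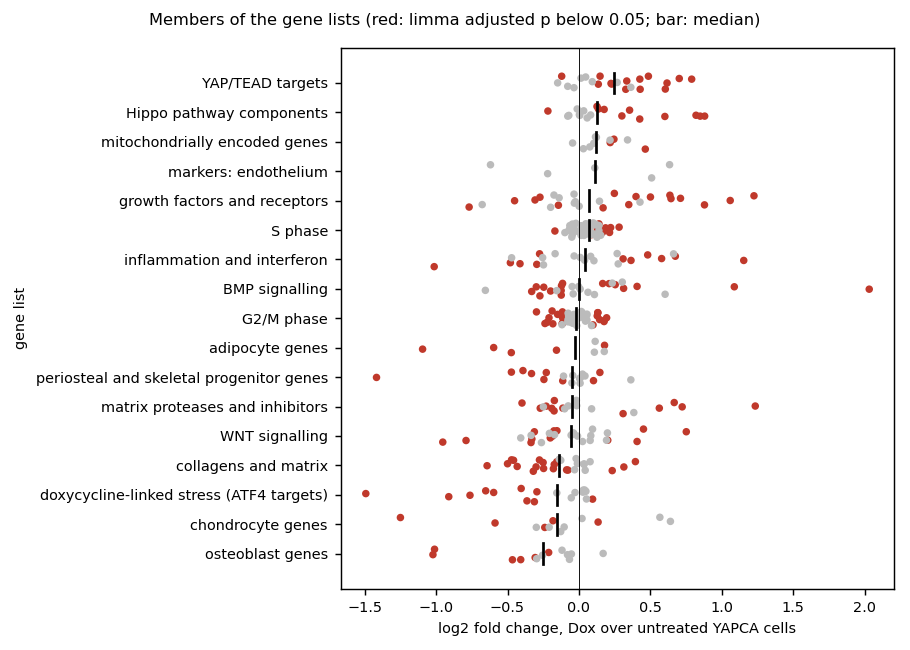
Log2 change (Dox over untreated YAPCA cells, n = 3 each) of each tested member of the 17 gene lists with at least 5 tested genes, in red where the limma adjusted p was below 0.05, with a bar at the list median. The median is 0.25 for YAP/TEAD targets and -0.26 for osteoblast genes.

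In all, 3757 of 13477 tested genes passed (27.9%), 1931 rising and 1826 falling, with a median absolute log2 change of 0.23. Of the genes that passed, 47 rose and 48 fell by more than 1 on the log2 scale, and 3647 had groups without overlap. Among all tested genes 41% had no overlap, against 10% by chance for 3 samples against 3. Of the 17 lists tested, 8 passed with camera's preset correlation of 0.01 and 0 with an estimated correlation, where 3 lists (YAP/TEAD targets, osteoblast genes and ATF4 targets) had an unadjusted p below 0.05. The authors' deposited table called 2668 of the tested genes with DESeq2, and 2664 of these were among the 3757, all in the same direction.

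The second comparison asked where chromatin opened or closed with Dox in YAPCA cells. Sites gained in accessibility outnumbered sites lost, with 26605 gained (87.2%) and 3891 lost (12.8%) among the 30496 sites at an FDR below 0.05 in the authors' deposited table. The median log2 fold in the authors' deposited table was 0.56 for gained and -0.53 for lost sites, and 3277 sites were gained and 200 lost by more than 1 on the log2 scale. All 4 sites nearest to Ccn2 in the authors' deposited table were gained, among them one over the gene at chromosome 10:24595231-24597479 (mm10) with a log2 fold of 0.73 (FDR = 2.65e-40). All 3 sites nearest to Ccn1 were gained in the authors' deposited table as well, with the largest log2 fold, 0.72, at chromosome 3:145644799-145645049, outside the gene. The 4 sites nearest to Ankrd1 had log2 folds of 0.39 to 0.58 and the 9 nearest to Amotl2 of 0.34 to 1.25 in the authors' deposited table, the latter highest at chromosome 9:102715605-102715882, outside the gene.

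In the authors' deposited table the single site of Lats2, inside the gene at chromosome 14:57709356-57709628, was gained at 0.47, and 2 sites inside Yap1, at chromosome 9:7962936-7963083 and 9:7965715-7965957, were gained at 0.66 and 0.54. Bmp4 had 0 listed sites assigned in the authors' deposited table. The gained sites with the smallest FDR in the authors' deposited table were a pair at X:156234622-156235393 and X:156454880-156455713, 172935 and 393224 bp from the nearest reference gene, the predicted Gm15155, with log2 folds of 4.91 and 5 (FDR = 3.95e-98 and 1.56e-87). They were followed in the authors' deposited table by a site at 8:64582812-64583444 outside Cpe, which encodes carboxypeptidase E (1.65), and intergenic sites at 13:25639878-25640498 (1.67) and 10:17364166-17364638 (1.65). Of the 5 lost sites with the smallest FDR in the authors' deposited table, 3 lay just outside Egr3 at 14:70085076-70085650 (-1.65), 14:70085781-70086094 (-1.62) and 14:70084342-70084591 (-1.53). The other two in the authors' deposited table were at 1:134073881-134075061 by the antiproliferative gene Btg2 (-0.68) and 7:45456443-45457513 by the glycogen synthase gene Gys1 (-0.49). Gained and lost sites lay inside a gene span, exons and introns together, in 59.3% and 62.0% of cases. The direction follows the headings of the main sheet of sites in the authors' deposited table, which a second sheet for chromosome 3 gives exchanged. No values per sample were used, so the spread behind each fold is that of the authors' DiffBind fit.

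The third comparison asked whether sites changed near genes whose RNA changed in YAPCA cells. Among genes that rose, 1220 of 1908 (63.9%) had a gained site assigned within 50 kb, against 3803 of 9309 tested genes that did not pass (40.9%; Fisher's exact test, two-sided, odds ratio 2.57, p = 4.08e-76). Among genes that fell, 416 of 1807 (23%) had a lost site, against 12.4% (odds ratio 2.11, Fisher's exact p = 5.49e-29). Edn1 and Adamts5, each with 6 gained sites, and Crim1, with 11, were among the former, and Egr3, with 6 lost sites, Cygb, with 3, and Ddit4, with 2, among the latter. Not every gene matched its sites: Thbs2 and Crocc2 fell with 6 and 4 gained and 0 lost sites, and Gas1 fell with 0 listed sites. Lost sites near genes that rose, at 12.8% against 12.4%, did not pass (odds ratio 1.03, Fisher's exact p = 0.676). Gained sites near genes that fell were slightly more frequent (44.9%, odds ratio 1.18, Fisher's exact p = 0.00159), which did not pass with sites at an FDR below 0.01 (odds ratio 1.1, Fisher's exact p = 0.0919). Both results depended on the background: among genes with any listed site, lost sites near genes that rose had an odds ratio of 0.636 (Fisher's exact p = 4.82e-09) and gained sites near genes that fell one of 0.604 (Fisher's exact p = 9.67e-07). There the share of one direction also drops when sites of the other direction are more frequent, so these 2 values do not show by themselves that such sites were rarer.

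Counted by site, 7% of the 4457 sites nearest to genes that rose were lost (Wilson 95% interval 6.3 to 7.8), against 13.4% of 10829 nearest to genes that did not pass (12.7 to 14) and 24.1% of 2529 nearest to genes that fell (22.5 to 25.8). The lost share near genes that fell exceeded that near genes that rose (Fisher's exact p = 7.62e-88). These intervals cover counting error only, and genes are not independent replicates. Both the intervals and this test count each site as independent, although sites of a gene share its RNA call. The sites nearest to genes that rose belonged to 1270 genes and those nearest to genes that fell to 970. Across the 6493 genes with a site, the mean fold of the sites in the authors' deposited table and the RNA change had a Spearman rho of 0.168 and a Pearson r of 0.154, with a permutation p of 1e-05 for the absolute rho, the smallest that 100000 permutations can give. With gene span and expression level in a logistic model, chosen after seeing the data, the odds ratios were 2.19 (95% interval 1.95 to 2.46) for gained sites and 2.00 (1.75 to 2.29) for lost sites.

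**Figure D3:**
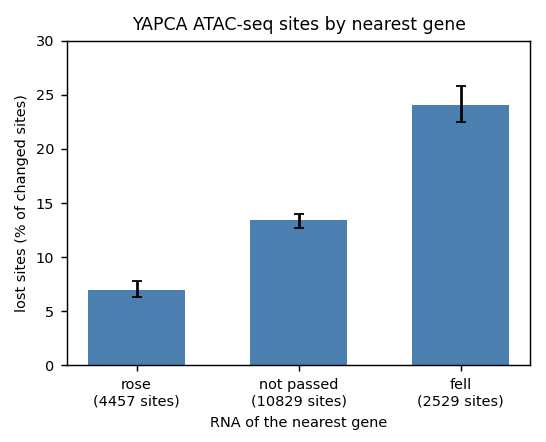
Share of changed YAPCA ATAC-seq sites that were lost (%, Wilson 95% intervals) by the RNA call of the nearest gene. The share is 7% for genes that rose, 13.4% for genes that did not pass and 24.1% for genes that fell.

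The fourth comparison asked what Dox did to RNA in wild-type cells, which lack the transgene. In the authors' deposited table, 23 genes rose and 75 fell at a DESeq2 adjusted p below 0.05, with log2 changes of -0.38 to 0.22. Among genes without overlap between groups and leaving out predicted genes, the authors' deposited table gave the largest rises to Ifitm3, an interferon-induced membrane protein (0.22), Olfml3 (0.19), the Groucho family corepressor gene Aes (0.18), the ribosomal stalk gene Rplp2 (0.17) and Paip2, a repressor of translation (0.17). Ifitm3 went from 7218 ± 406 to 8382 ± 535 normalised read counts (SD, n = 3), and 6 of the genes that rose encode ribosomal proteins. By the same filters, the largest falls in the authors' deposited table were those of the imprinted noncoding RNA Meg3 (-0.34), Leng8 (-0.31), Col7a1, type VII collagen (-0.30), the scavenger receptor gene Stab1 (-0.26) and the dynein heavy chain gene Dync1h1 (-0.26). Meg3 went from 13725 ± 824 to 10824 ± 1186 and Dync1h1 from 12245 ± 139 to 10256 ± 603 normalised read counts (SD, n = 3). Stab1 stood at a mean of 2432 normalised read counts in the authors' deposited table and at 16.8 in the YAPCA libraries. Yap1, Ccn1, Ccn2, Ankrd1 and Bmp4 were not among the 98 genes of the authors' deposited table. Groups did not overlap for 97 of the 98, which were listed because they passed, where chance gives 10%. The lowest mean in the authors' deposited table was 1970 normalised read counts and its adjusted p-values fit about 3148 tests, so genes below that level are not compared here.

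Set beside the YAPCA cells, the genes that fell in wild-type cells did not fall there as a group. Of these 75 genes, 26 rose, 11 fell and 38 did not pass in YAPCA cells, with a median YAPCA log2 change of 0.06. Of the 23 that rose in wild-type cells, 3 rose, 6 fell and 14 did not pass in YAPCA cells, with a median of -0.05. Thbs1, for example, had a log2 change of -0.13 in the authors' deposited table for wild-type cells and one of 0.39 ± 0.030 (SE) in YAPCA cells. Olfml3 and Aes had log2 changes of -0.28 and -0.19 in YAPCA cells. The tables were normalised separately, and the difference between genotypes was not tested gene by gene.

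**Figure D4:**
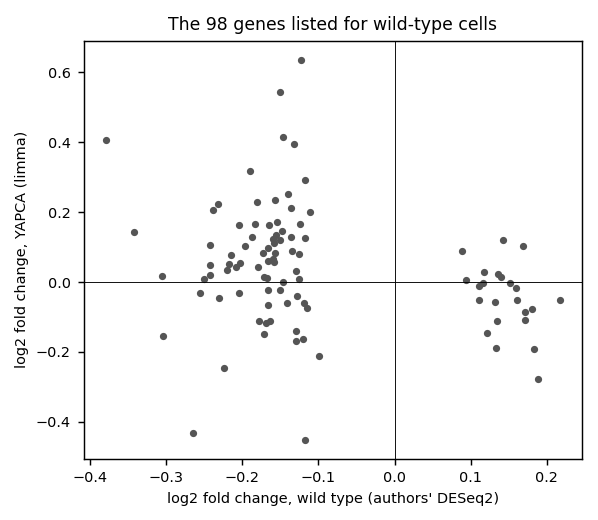
Log2 change with Dox of the 98 genes listed for wild-type cells, in wild-type cells (authors' DESeq2, horizontal axis) and in YAPCA cells (limma, vertical axis), with a point per gene. The 75 genes that fell in wild-type cells have a median of 0.06 in YAPCA cells, and the 23 that rose one of -0.05.

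The last comparison asked where chromatin changed with Dox in wild-type cells. The authors' deposited table lists 42 sites, 36 with a positive and 6 with a negative log2 fold, from -0.42 to 0.44. It does not name the order of the groups, so the sign is given as listed. In the authors' deposited table the positive sites with the smallest FDR lay inside Pde3a, a phosphodiesterase gene, at 6:141249393-141250145 (0.44, FDR = 0.0017), inside the type V collagen gene Col5a1 at 2:27886172-27886639 (0.41), inside Auts2 at 5:131537633-131538901 (0.37), by 1110002L01Rik at 12:3426511-3427010 (0.30) and inside Wdsub1 at 2:59882140-59882750 (0.44). The negative ones in the authors' deposited table lay by the annexin gene Anxa1 at 19:20371192-20373206 (-0.25), by Platr6 at 10:21785601-21786207 (-0.25), by the immediate-early genes Egr1 at 18:34864992-34865985 (-0.29) and Fos at 12:85477318-85477580 (-0.42), and inside Lima1 at 15:99852597-99853366 (-0.29). Of the 42 sites, 4 overlapped a listed YAPCA site by at least 1 bp, and 2 of the 4 had the same sign in the authors' deposited table. The lowest mean log2 concentration among them was 8.91, against 2.97 for YAPCA, and 6152 YAPCA sites lay at or above 8.91 in the authors' deposited table, so the counts of the genotypes do not rest on sites of the same range.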

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

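The test of gene span was set before its result was seen. So were the comparison of both genotypes for the wild-type genes and that of lost shares between genes that fell and genes that rose. The names of the wild-type genes had been read by then. The counts of splits, the subtraction of an offset, the 24.1% lost share and the tests of the X chromosome sites were chosen only after the result was seen.

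Of the genes named here, 5 drew attention because all samples moved in opposite directions with Dox in wild-type and YAPCA cells, and the difference between the genotypes was not tested. Aes, Olfml3 and Paip2 rose in wild-type cells in the authors' deposited table and had log2 changes of -0.19, -0.28 and -0.11 in YAPCA cells, and Thbs1 and Itgav fell in wild-type cells in the authors' deposited table and changed by 0.39 and 0.15 in YAPCA cells. Of the 98 genes listed for wild-type cells, 37 had such opposite changes without overlap in either genotype.

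The first pattern is the set of 98 small changes in wild-type cells, where Dox has no transgene to act on. A Dox response that both genotypes share would lower the same genes in YAPCA cells, unless the transgene moved them the other way. The genes that fell in wild-type cells had a median YAPCA log2 change of 0.06, at percentile 99.79 of 10000 random lists of like expression. Those that rose had one of -0.05, at percentile 0.52. No shared response was thus seen, but one masked by the transgene cannot be excluded. The lists were not matched on gene span. Among YAPCA genes at or above the lowest wild-type mean, those that fell had a median span of 26919 bp and those that rose one of 35359 bp. A difference in RNA recovery or fragmentation linked to gene length between libraries is a candidate explanation, tested on gene span alone. The genes that fell had a median gene span 10.58 times that of the genes that rose (39224 against 3709 bp, two-sided permutation p = 2e-05). This is a doubled one-sided p and the smallest that 100000 permutations can give so. A span includes introns, so it is not the length of the mature RNA, which was not compared. A response of wild-type cells to Dox that differs by genotype stays open, as the span of a gene goes with other properties and no test here tells these apart. No biological explanation was tested beyond the shared response.

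The second pattern is the excess of gained over lost YAPCA sites. The direction of sites went with that of the RNA, as the lost share was 17.1 percentage points higher near genes that fell than near genes that rose (Fisher's exact p = 7.62e-88). That p counts sites of the same gene as independent, so it overstates the evidence. Whether changes that follow the RNA add to the excess stays open, and they are not the whole of it, since 1931 genes rose and 1826 fell and even near genes that fell only 24.1% of sites were lost. An offset between groups from the normalisation of the ATAC-seq reads may contribute and cannot be told apart here, because the test could use only sites listed as changed: after subtracting 0.27, the median log2 fold of the strongest 10% of sites, 1224 sites lay above 1 and 826 below -1, a ratio of 1.48. Counts for unchanged sites would decide it.

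The third pattern is a group of 6 sites on the X chromosome, between 156234622 and 156456750 (mm10), that were nearly closed in untreated YAPCA cells and open with Dox, with a median log2 fold of 4.97 in the authors' deposited table. The 6 sites were picked for a log2 fold over 3, so other sites lie lower by selection. The sign of the difference in medians, 4.33, was thus fixed in advance. The other 13 listed sites within 2 Mb had a median log2 fold of 0.64 and a highest of 1.57. A gain of copies of the whole surrounding region would have raised these sites alike, so their own low folds argue against it. A regulatory change of nearby genes could not be tested, with 0 tested genes within 500 kb. Sequence shared with the transgene or reads from a repeat stays open and was not tested, since no genome sequence was used here.

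The YAPCA count of 3757 genes was given by 1 of the 10 splits of the 6 libraries, the real one, and the highest of the other splits gave 0 genes with limma. For the gene lists, 1 of the 10 splits gave as many as 8, and the others gave 0 to 5, each with 0 genes called. Lists thus passed camera's preset correlation in splits other than the real one. Those splits still divide the Dox samples unevenly, so they are not free of the Dox effect. The 10 splits of the 6 libraries are too few for a share under 0.05.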

How the results depend on the processing

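Alternatives were set before the data were examined, except the counts limited to wild-type levels, the logistic model and limma over the listed wild-type genes, which were chosen only after the result was seen.

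The count of 3757 YAPCA genes stayed within 1.5 times under DESeq2, edgeR, TMM scaling, pseudocounts of 0.5 and 5 and both filters (2668 to 3824), and ranged from 2879 to 3583 when a library was left out. It was 2348 at an adjusted p below 0.01, 95 with an absolute log2 change over 1, and 1247 among genes at or above the lowest wild-type mean, all fewer by construction. In wild-type cells 41 genes were left at 0.01 and 0 beyond 1 on the log2 scale in the authors' DESeq2 values, and limma over the listed genes gave 95 to 98 when a library was left out, which tests nothing, as the genes were listed because they passed. Other count tools, scalings and filters were not run for wild-type RNA-seq, whose table lists the 98 passed genes alone, nor was the motif test. Gained YAPCA sites numbered 3277 beyond 1 on the log2 scale, lost sites 1204 at an FDR below 0.01 and 200 beyond 1, and all sites 19450, 3477, and 6152 at or above the lowest wild-type concentration. Wild-type sites numbered 1 at 0.01 and 0 beyond 1 in the authors' DiffBind values. The odds ratio of gained sites near genes that rose stayed between 2.19 and 2.89 and that of lost sites near genes that fell between 2 and 2.16 under every distance, threshold, background and model tried.

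Whether the replicate numbers pair the YAPCA libraries stays open. Same-numbered libraries had correlations of -0.001, 0.036 and 0.085 for replicates 1, 2 and 3. The highest correlations with another number were 0.051, 0.03 and -0.025, so only replicate 1 correlated more with another number. A replicate block gave 4350 genes, 8 lists and 98 wild-type genes, and added a call for Yap1 (-0.07). For ATAC-seq, no paired analysis was possible because the values are the authors' fits with no samples.

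Of the 17 lists tested, camera called 8 at its preset correlation and 0 with an estimated correlation, where 3 had an unadjusted p below 0.05. Correlation among genes alone does not account for this loss. The ATF4 and osteoblast lists had estimated correlations of -0.037 and 0.013, below or near the preset 0.01. Their unadjusted camera p still went from 3.54e-05 to 0.0109 and from 7.19e-06 to 0.0116. The estimated form also takes its degrees of freedom from the few libraries, not from the many genes. A call lost there can thus reflect low power and does not by itself show correlated genes. The rank-based test called 7 of the 8, and 7 to 8 passed when a library was left out. With fry 11 lists passed, 7 of the 8 and the adipocyte, BMP, chondrocyte and growth factor lists. Lists that did not pass changed direction in some settings. The BMP list gave adjusted p = 0.622 with a mean of at least 50 and 0.995 with the replicate block (0.0196 to 0.995 over all settings). The matrix protease list gave 0.995 with the block and 0.198 with fry, and 0.873 to 0.948 when a library was left out, and the inflammation list 0.176 to 0.813. The cause was not tested. Among 99 named genes, 1429 of 1459 values kept direction and call, 16 lost the call, 6 gained it and 8 changed sign, all of genes that had not passed: Chrna1 was at -0.02 with edgeR and -0.16 to 0.30 when a library was left out, Csf1r at -0.12 to 0.02, Acp5 at -0.78 to 0.13 and Cd68 at -0.01 to 0.22. Acta1 lost its call with DESeq2 and when any library other than untreated replicate 3 was left out, Comp with DESeq2 and without untreated replicate 2 or Dox replicate 1, and mt-Cytb with DESeq2 and without untreated replicate 1. DESeq2 did not call mt-Nd4. Calls were added for Yap1, for Tek, for Cd14 with a mean of at least 50 and for mt-Co2 without untreated replicate 3 (0.50). Chrna1 and Acp5 stood below 20 normalised read counts, and whether depth limits these values was not tested.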

Other observations

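The comparison of gene set scores between genotypes, the levels of Stab1, Igfbp2 and Cspg4 and the sites by chromosome, strength and list were chosen only after the result was seen.

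The authors' deposited table of gene set scores gives each library a score for sets of a public collection. In YAPCA cells the authors' deposited table has 552 of 4320 sets at an FDR below 0.05, 296 higher and 256 lower with Dox. The highest rises in the authors' deposited table were those of the nuclear pore reformation set of Reactome (a difference of 0.961 in mean score), the set of rRNA modification (0.927), the sets on Rev protein and its nuclear import (0.874 and 0.853) and the set of mature mRNA transport dependent on SLBP (0.83), which hold nuclear pore and ribosome biogenesis genes. The nuclear pore reformation score went from -0.477 ± 0.0743 to 0.484 ± 0.0355 (SD, n = 3). The lowest in the authors' deposited table were glycosaminoglycan degradation (-0.965), a cancer microenvironment set (-0.876), a set of RhoA-transformed cells (-0.846), p53 targets (-0.838) and a set of ROCK signalling (-0.825). Of the sets that name YAP, the authors' deposited table has the Hippo-YAP signalling set at 0.087 (FDR = 0.852), the YAP/TAZ mechanoregulation set at -0.0541 (FDR = 0.882) and a set on miR-509-3p, YAP1 and extracellular matrix at -0.665 (FDR = 0.0279).

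In wild-type cells the authors' deposited table has 523 of 4333 sets at an FDR below 0.05, 418 higher and 105 lower with Dox. Translation led the rises in the authors' deposited table, with the KEGG ribosome set at 0.833, a serum and rapamycin response set at 0.822, the set of protein targeting by the signal recognition particle at 0.821, translation elongation at 0.81 and selenoamino acid metabolism at 0.807. The ribosome score went from -0.388 ± 0.331 to 0.445 ± 0.326 (SD, n = 3). The largest falls in the authors' deposited table were an ERBB2 metastasis set (-0.819), a type II diabetes set (-0.693), laminin interactions (-0.67), VEGFR2-mediated proliferation (-0.627) and a set lowered by trichostatin A (-0.619). Groups did not overlap for 31.6% of sets in YAPCA cells and 16.8% in wild-type cells, where chance gives 10%. Across the 4320 sets in both tables the differences had a Pearson r of -0.122 and a Spearman rho of -0.131, over sets that share genes and are not independent replicates. Of 118 sets with an FDR below 0.05 in both, against 66.8 for independent lists, 51 had the same sign and 67 the opposite sign in the authors' deposited table.

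Stab1, a scavenger receptor gene of macrophages and sinusoidal endothelium, stood at a mean of 2432 normalised read counts in the wild-type libraries and 16.8 in the YAPCA libraries, a ratio of 145. Igfbp2 and Cspg4 had ratios of 6.04 and 4.67. The other genes listed for wild-type cells had ratios of 0.575 to 1.92, and the median of all 98 was 1.28. The tables were normalised separately and hold no shared library, so the ratios are values with no test.

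Gained sites were spread over the chromosomes. Of the changed YAPCA sites of the X chromosome in the authors' deposited table, 94.3% were gained, with a median log2 fold of 0.64, against 82.6% with a median of 0.46 on chromosome 11, the lowest share. The share gained went with the strength of the site in the authors' deposited table, from 78.9% in the weakest 10% of sites to 97.4% in the strongest 10%, while the median fold went from 0.95 to 0.27. Only sites that passed are listed, and a weak site needs a larger fold to pass. The course of the median fold may thus come from this selection. Sites assigned to the YAP/TEAD target list numbered 121 gained and 5 lost (4% lost), and those of the ATF4 target list 9 gained and 6 lost (40% lost), against 12.8% lost over all sites in the authors' deposited table. Other lists reached further both ways, with 28 gained and 0 lost for G2/M genes and 2 gained and 2 lost for osteoclast markers, and no difference was tested.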
